A study of Homo sapiens with 6 samples.

How the data were processed

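Hep3B, an established human hepatocellular carcinoma cell line, was profiled on 6 Illumina expression BeadChip arrays. Per the labels, 3 samples were treated for 24 h with the solvent DMSO (control) and 3 for 24 h with sorafenib, an inhibitor of RAF and receptor tyrosine kinases, at a stated dose of 3 mM. Culture work with this drug normally uses micromolar doses, so the unit may be a slip, which could not be checked against the data. Per the labels' protocols, total RNA was purified on spin columns, treated with DNase I and converted to biotinylated cRNA with a TargetAmp-Nano kit. The labels number the samples of each group 1 to 3 and do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. The other cell lines that the design text names were not analysed here. Scanner software, slide and scan date are not given in the sources used here.

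The authors deposited, per the file headers, a non-normalized bead-averaged intensity and a detection p-value for each of 47321 probes on every array. The authors also deposited a table of log2 values with no stated method. These were compared with the intensities: taking log2 of the raw intensity and quantile-normalizing over the 6 arrays gave the deposited log2 values with a largest difference of 5.0e-07, and each column had a median of 6.79. Their scale and normalization were thereby settled, and they served as an alternative, the same in processing as the one without background correction.

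Intensities were background-corrected with limma 3.58.1 in R 4.3.3 by the neqc method, which estimates the background from the detection p-values (offset 16), then quantile-normalized and put on the log2 scale. A probe was tested when its detection p was under 0.01 on at least 3 of the 6 arrays, which left 16909 probes. Each was fitted with lmFit and eBayes (sorafenib minus control, two-sided, no block), and p-values were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. Errors of log2 differences are limma's moderated standard errors (SE), with 3 arrays per group. The number of arrays limits the precision.

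Probe names came from the platform annotation supplied with the values: 30112 probes had 1 gene symbol, 8 had several and 17201 had none. Of the named probes, 30073 matched a current gene by Entrez ID, and no symbol needed updating. Of the probes tested, 13675 had 1 gene and 3234 did not. A gene was represented by its brightest tested probe, chosen without reference to the groups, which gave 10598 genes. Of 2547 genes with several tested probes, 12 had probes called in opposite directions. Probes for close paralogs (metallothioneins, histones, ribosomal proteins, aldo-keto reductases) may bind each other's transcripts, and single members of these families are uncertain.

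Where a gene's probe was not detected on any array of a group, its level there is only a bound. The ratio is then written as "at least N-fold", from the bright group's mean against the dim group's mean of, per array, the higher of the dimmest detected signal and the probe's own signal.

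The lists of genes were fixed before the data were examined, as were the groups, the tests and the alternative analyses. There were 41 lists holding 867 genes, of which 807 had a named probe and 650 were measured. The 37 lists with at least 5 measured genes were tested against all other genes with limma's camera at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 37. Beside it stand camera with the correlation estimated for each list, and fry, which asks whether a list's genes move one way on balance without comparing them with other genes. A list's median was also set against 10000 random lists in which each member was replaced by 1 of the 50 non-members nearest in mean intensity; this matching replaced a coarser matching in intensity bins after results of the latter had been seen.

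Genes were named by a rule fixed at the same time: the 10 largest rises and the 10 largest falls, by fitted values, past the threshold with no overlap between groups and no placeholder symbol, every measured member of the protein disulfide isomerase (PDI) family, and of any other list up to the 3 members with the largest differences, or up to 6 where the list is described in full. Any other gene named was chosen after its values were seen.

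Alternatives were other background corrections, other between-array normalizations, the deposited log2 values, other filters on dim probes, the replicate number as a block, other variance models, array weights, the median over a gene's probes and leaving out each array. Centring on the tested probes was added after the data had been seen. In simulated data with the real probes' levels and spread (16909 probes, 3 against 3), each size of change was given to 50 probes. The test recovered 2% of probes changed by 0.25 log2, 42% at 0.5, 68% at 1 and 96% at 2, with 4 false calls among 108. With so few changed probes the adjusted threshold was stricter than in the real data, where 5778 probes passed, so recovery there may differ. On simulated lists of 20 genes shifted by 0.5, camera called 50 of 50 shifted lists and 0 of 50 unshifted ones over 10598 genes. Simulated genes were drawn independently, so this does not cover lists of correlated genes. Figures were drawn with matplotlib 3.10.9.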

Results

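Gene expression was measured in Hep3B hepatocellular carcinoma cells after 24 h with sorafenib or with its solvent, on 3 arrays per group. Between 16214 and 17380 of 47321 probes were detected on an array (34.3% to 36.7%), and raw median intensities lay between 106 and 117. Normalized values of the tested probes correlated across probes at 0.992 to 0.997 within a group and at 0.977 to 0.982 between groups. The first principal component held 68% of the variance and separated sorafenib from control, and the second (13.5%) set replicate 3 of each group apart from the others. The study's title concerns PDI inhibition alongside sorafenib. By their labels, these 6 samples received sorafenib or solvent and no PDI inhibitor, so the comparison asks what sorafenib alone changed.

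PRPH, the neuronal intermediate filament peripherin, was not detected in control cells and was at least 15.7-fold higher with sorafenib (limma adjusted p = 3.2e-06, n = 3 per group). LAMP3, a lysosomal membrane protein, rose 14.8-fold (log2 3.89 ± 0.12, SE), although a second LAMP3 probe, dimmer on average, rose by only 0.67. SERPINC1, which encodes antithrombin, was likewise undetected in control cells and rose at least 5.44-fold. The chemokine genes CXCL5 and CCL20 showed the deepest falls, 8.20-fold (log2 -3.04 ± 0.24) and 5.42-fold (log2 -2.44 ± 0.08). EGR1, an immediate early transcription factor, fell 4.49-fold and EDN1, the endothelin 1 precursor, 4.53-fold.

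By fitted values, the other large rises were AKNA (6.35-fold), the hexokinase-related HKDC1 (6.27-fold), NIBAN1 (4.71-fold), ADAMTSL2 (at least 3.22-fold), the sterol esterifying enzyme SOAT2 (at least 3.32-fold), the metallothionein MT1G (at least 3.03-fold) and the interferon-induced GTPase MX1 (at least 2.81-fold). A second SOAT2 probe, dimmer on average though not in control cells, had a fitted log2 rise of 1.04, against 2.01 on the probe used. The other large falls were SAA4 (4.61-fold, detected on 2 of 3 sorafenib arrays), the gap junction gene GJA1 (3.77-fold), CBLN2 (3.68-fold), the chemokine CXCL1 (3.67-fold), HOXD1 (at least 2.67-fold) and ODAM (at least 2.26-fold). Fitted values of genes written with a bound lie below detection in 1 group, so the rank of these genes is uncertain; at their bounds HOXD1 and ODAM fell less than CXCL8 and PDGFRA (3.58-fold each). Limma's adjusted p for these 20 genes was at most 0.000783. Among all probes, 5778 of 16909 passed the threshold, 3031 higher and 2747 lower (52.5% higher). Centring each array on its median in place of quantile normalization gave 4439 probes, 69.5% of them higher. That median is taken over all 47321 probes, most of them undetected. Centring on the tested probes gave 5729 probes, 50.9% of them higher. That centring sets the tested probes' median equal on every array, so a near-even split was largely built in. It cannot show a shift shared by most genes. At the gene level, 3888 of 10598 genes passed, 2086 higher and 1802 lower, and 295 differed at least 2-fold (172 higher, 123 lower). The count at 2-fold was 132 without background correction (the same processing as the deposited log2 values) and 150 with normexp at an offset of 50. On all 3 sorafenib arrays 49 probes had a detection p under 0.01 while staying over 0.05 on all 3 control arrays, a stricter rule than the one for bounds, and 16 probes showed the reverse.

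**Figure D1:**
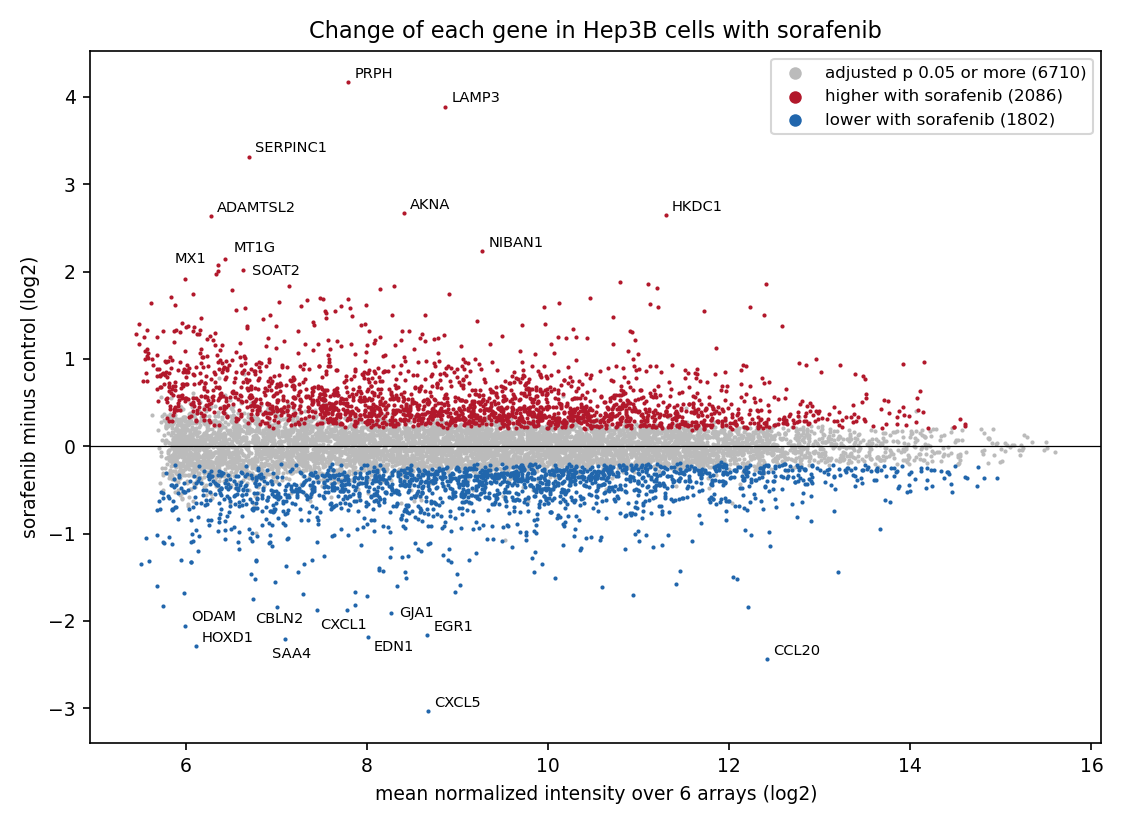
Each point is 1 of 10598 genes, with its mean normalized intensity over the 6 arrays (log2) on the x axis and the difference sorafenib minus control (log2) on the y axis. Red points (2086) were higher and blue points (1802) lower at an adjusted p under 0.05; the 10 largest rises and 10 largest falls are labelled, from PRPH at 4.17 to CXCL5 at -3.04, and genes undetected in 1 group are drawn at their fitted values.

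**Figure D2:**
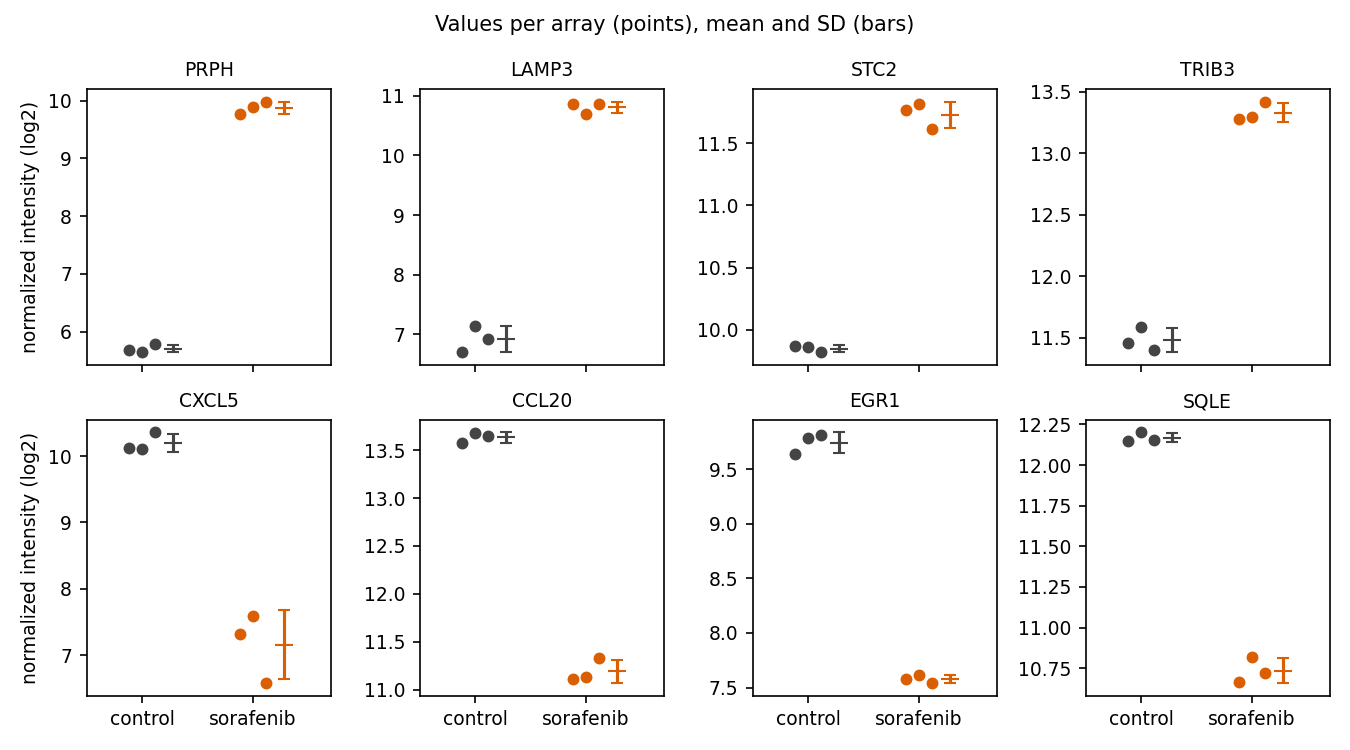
Normalized log2 intensity of 8 genes on each of the 6 arrays (points), with the mean and SD of each group of 3 beside them; each panel has its own y axis, which does not start at 0. PRPH, LAMP3, STC2 and TRIB3 lie higher on all 3 sorafenib arrays than on any control array, and CXCL5, CCL20, EGR1 and SQLE lie lower.

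The PDI family is named for oxidoreductases that form and rearrange disulfide bonds in the endoplasmic reticulum (ER), and its members were not separated by whether they have that activity. Of its 15 measured genes, 4 rose, 1 fell and 10 did not pass (6 passed when adjusted over the list alone). ERP27 rose 1.89-fold (log2 0.92 ± 0.06, SE, limma adjusted p = 0.000120), DNAJC10 1.59-fold (0.67 ± 0.09), ERP29 1.30-fold (0.38 ± 0.08) and PDIA5 1.23-fold (0.30 ± 0.08), while TMX1 fell 1.31-fold (-0.39 ± 0.08). P4HB, the founding member of the family, differed by 0.04 ± 0.08, with a 95% interval of -0.14 to 0.22. PDIA6 differed by 0.13, PDIA4 by -0.10, TXNDC5 by 0.05, TXNDC12 by 0.20 (adjusted p = 0.0509), TXNDC11 by 0.19, TXNDC16 by -0.24, TMX2 by -0.03, TMX3 by -0.02 and TMX4 by -0.17, none past the threshold. As a list the family did not stand apart from other genes (median log2 0.05, camera adjusted p = 0.282). Without sorafenib replicate 1 the number of its genes past the threshold was 3, and PDIA5 and ERP29 no longer passed.

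The partners of PDI in oxidation held 2 risen genes among 11 and none fallen (2 adjusted over the list alone, camera adjusted p = 0.261): the peroxidases GPX7 (1.82-fold) and GPX8 (at least 1.21-fold). QSOX1, a sulfhydryl oxidase, differed by 0.37 without passing. Among 19 ER chaperones and glycoprotein folding factors, 3 rose, 3 fell and 13 did not pass (6 adjusted over the list alone). The co-chaperone DNAJB9 rose by 0.62 ± 0.10, the HSP70-related HYOU1 by 0.54 ± 0.12 and CNPY2 by 0.41 ± 0.07, and MANF fell by 0.42 ± 0.06, DNAJC3 by 0.36 ± 0.09 and SDF2L1 by 0.27 ± 0.07. The list's median was -0.05, its mean 0.03 and camera's direction upward, so the signs differed (camera adjusted p = 0.982). The XBP1 and ER-associated degradation list had 5 of 19 genes higher, none lower and a median of 0.17 (5 adjusted over the list alone), led by DNAJB9, the mannosidase-like EDEM1 (0.39) and DERL1 (0.35). It did not pass as a list (camera adjusted p = 0.0776).

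**Figure D3:**
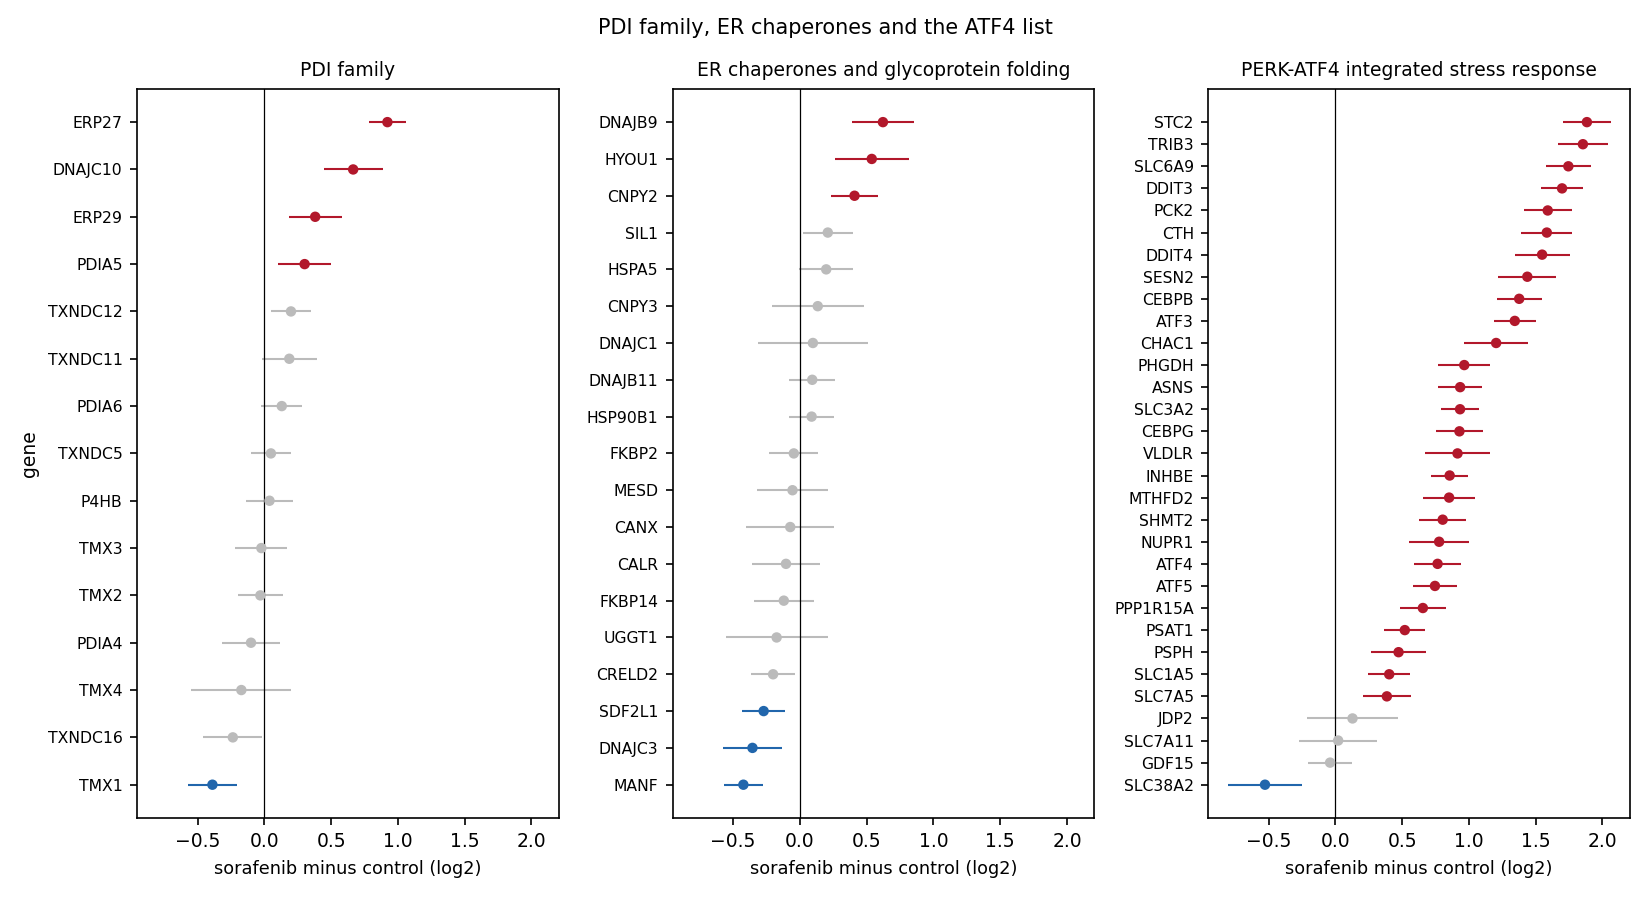
Difference sorafenib minus control (log2, x axis) of each measured gene of 3 lists (y axis): 15 PDI family genes, 19 ER chaperones and 31 genes of the integrated stress response. Points are estimates and lines 95% intervals over 3 arrays per group, with red for higher, blue for lower and grey for not past an adjusted p of 0.05; 27 of the 31 genes on the right lie above 0 and past the threshold, against 4 of 15 and 3 of 19 in the others.

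The list of integrated stress response genes, named for PERK and ATF4, rose with a median log2 of 0.91 (camera adjusted p = 2.1e-14, and adjusted p = 0.0328 with an estimated correlation). PERK activity was not measured, so what drove the rise was not tested. Of 31 measured genes, 27 rose, 1 fell and 3 did not pass (28 adjusted over the list alone). The secreted glycoprotein gene STC2 rose 3.69-fold (log2 1.88 ± 0.08, SE), the pseudokinase gene TRIB3 3.61-fold (1.85 ± 0.08), the glycine transporter gene SLC6A9 3.35-fold, the transcription factor DDIT3 (CHOP) 3.24-fold, mitochondrial PCK2 3.01-fold and the cystathionine lyase gene CTH 3.00-fold. ATF4 itself, chosen after its value was seen, rose by 0.77 ± 0.08, and the single member that fell was the amino acid transporter SLC38A2 (-0.53 ± 0.12). Cytosolic tRNA synthetases, which charge tRNAs with amino acids, rose with a median of 0.53 (camera adjusted p = 0.000312, but adjusted p = 0.0679 with an estimated correlation). In that list 11 of 18 genes rose and 1 fell (12 adjusted over the list alone), led by WARS1 (2.19-fold), SARS1 (1.85-fold) and IARS1 (1.65-fold).

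The mitochondrial stress list rose less, by a median of 0.16 with 6 of 14 genes higher and none lower (8 adjusted over the list alone, camera adjusted p = 0.0433, adjusted p = 0.224 with an estimated correlation). Its protease gene LONP1 rose 1.89-fold, the transcription factor ATF5 1.68-fold and the co-chaperone DNAJA3 1.46-fold. This call was lost in 3 of the 6 fits that left out 1 array (adjusted p 0.0329 to 0.0664 over the 6), with median centring (adjusted p = 0.144), with centring on the tested probes (0.104) and with the median over a gene's probes (0.0966). Among 19 apoptosis regulators, 5 rose and 2 fell (8 adjusted over the list alone, median 0.02, camera adjusted p = 0.704). The BH3-only genes HRK and BMF rose 3.22-fold and 1.61-fold and the death receptor gene TNFRSF10B 1.82-fold. The autophagy and lysosome list had 4 of 25 genes higher and 3 lower (7 adjusted over the list alone, camera adjusted p = 0.982), including the kinase ULK1 (0.50) and the lysosomal enzymes NEU1 (-0.49) and GLA (-0.35). Its median was 0.03 while its mean and camera's direction were below 0.

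Genes transcribed downstream of ERK, the kinase that RAF activates, fell with a median of -0.49 (camera adjusted p = 3.5e-06, but adjusted p = 0.0608 with an estimated correlation). Of 16 measured, 13 fell and 1 rose (14 adjusted over the list alone). After EGR1, the largest falls were IER3 (2.83-fold), the feedback inhibitors SPRY4 (2.42-fold), DUSP6 (1.96-fold) and SPRY1 (1.76-fold), and the receptor kinase EPHA2 (2.10-fold). The member that rose was MYC (0.40 ± 0.06). Only 3 genes of the receptor kinase and RAF list were measured, too few for a list test: PDGFRA fell 3.58-fold, PDGFRB at least 1.56-fold, and ARAF differed by -0.05 without passing (2 past when adjusted over the list alone). Growth factor receptors and ligands had 5 of 15 genes higher and 1 lower (6 adjusted over the list alone, median 0.04, camera adjusted p = 0.456), with VEGFA up by 0.67 and EREG by 0.44. IGF2 differed by -1.07 ± 0.37 on its brightest probe without passing (adjusted p = 0.0638), while a second probe passed (-0.92, adjusted p = 0.0411).

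Both cell cycle lists fell and held with an estimated correlation (adjusted p = 0.0328 for each). In the list of G1/S and DNA replication genes, 25 of 31 fell and none rose at the threshold over all genes (26 adjusted over the list alone, 1 of them higher), with a median of -0.43 (camera adjusted p = 1.4e-09). The ribonucleotide reductase subunit RRM2 fell 3.01-fold (log2 -1.59 ± 0.07), UHRF1 2.02-fold, thymidine kinase TK1 2.00-fold, cyclin CCNE1 1.98-fold, PCNA 1.75-fold and FEN1 1.58-fold. In the G2/M and mitosis list, 31 of 37 fell and none rose (32 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 3.5e-12). DLGAP5 fell 1.93-fold, the kinase PLK1 1.68-fold, the kinesins KIF20A 1.63-fold and KIF23 1.62-fold, and the proliferation marker MKI67 at least 1.68-fold. Replication-dependent histone genes fell with a median of -0.70 (8 of 9, 8 adjusted over the list alone, camera adjusted p = 4.2e-05, adjusted p = 0.117 with an estimated correlation), including H2BC5 (2.46-fold), H2AC18 (1.86-fold) and H2AC6 (at least 1.48-fold). CDK inhibitors and p53-responsive genes were split, 4 of 18 higher and 5 lower (9 adjusted over the list alone, median 0.03, camera adjusted p = 0.569), with GADD45A up 2.61-fold and BTG1 up 1.41-fold.

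Cholesterol synthesis and uptake had the lowest median of any tested list, -0.95 (camera adjusted p = 3.0e-09, adjusted p = 0.0328 with an estimated correlation). Of 18 genes, 15 fell, 1 rose and 2 did not pass (17 adjusted over the list alone). The epoxidase gene SQLE fell 2.70-fold (log2 -1.43 ± 0.07), the sterol sensor INSIG1 2.46-fold, MVD 2.40-fold, LSS 2.20-fold, IDI1 2.14-fold and NSDHL 2.12-fold. In fatty acid synthesis 7 of 12 genes fell and 2 rose (10 adjusted over the list alone, median -0.36, camera adjusted p = 0.0433, adjusted p = 0.379 with an estimated correlation). The desaturases SCD and FADS1 fell 1.82-fold and 1.47-fold, and the acyltransferase GPAM rose 2.14-fold. This call was lost in 4 of the 6 fits that left out 1 array (adjusted p 0.0343 to 0.0823 over the 6), with detection required on all 6 arrays (0.0504) and, narrowly, with centring on the tested probes. Fatty acid oxidation genes rose with a median of 0.16, 8 of 18 higher and none lower (8 adjusted over the list alone, camera adjusted p = 0.0153, adjusted p = 0.165 with an estimated correlation). They included ACADL (at least 1.77-fold), EHHADH (1.73-fold) and ECI1 (1.72-fold), and their median was 0.07 without sorafenib replicate 3.

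In glycolysis 2 of 19 genes rose and 6 fell (8 adjusted over the list alone, median -0.14, camera adjusted p = 0.0631). The regulator PFKFB3 fell 2.13-fold, while ENO2, detected on 2 of 3 control arrays, rose by 0.77 and PFKP rose at least 1.03-fold. The hypoxia list was split evenly, 4 of 18 higher and 4 lower (10 adjusted over the list alone, median -0.06, camera adjusted p = 0.544), with NDRG1 up by 0.98, LOX down by 0.85 (log2 -0.85) and VEGFA up. Respiratory chain genes had 2 of 37 higher and 7 lower (7 adjusted over the list alone, median -0.04, camera adjusted p = 0.299), including UQCRB (-0.53, with a second probe at 0.00), NDUFA2 (-0.47) and NDUFB3 (-0.40).

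Genes of inflammatory cytokines and NF-kB targets fell, 9 of 12 lower and none higher (9 adjusted over the list alone), with a median of -0.65 (camera adjusted p = 1.4e-05, but adjusted p = 0.0560 with an estimated correlation). Besides CXCL5, CCL20 and CXCL1, the interleukin 8 gene CXCL8 fell 3.58-fold (log2 -1.84 ± 0.11), IER3 2.83-fold and the adhesion molecule ICAM1 1.59-fold. In the TGF-beta and mesenchymal list 10 of 17 genes fell and 3 rose (13 adjusted over the list alone, median -0.50, camera adjusted p = 0.0108, adjusted p = 0.117 with an estimated correlation). The matricellular gene CCN2 fell 2.86-fold and the actin-binding TAGLN 2.42-fold, whereas the transcription factor SNAI2 rose at least 1.81-fold on its brighter probe and differed by 0.35 on the other, without passing. Acute phase genes went both ways, 7 of 13 higher and 4 lower (12 adjusted over the list alone, median 0.29, camera adjusted p = 0.462), with SERPINA3 up 2.76-fold against SAA4 and JUNB (2.04-fold) down. The interferon list had 4 of 15 higher and 2 lower (9 adjusted over the list alone, median 0.19, camera adjusted p = 0.0776), with MX1, IFIT1 (at least 1.43-fold) and IRF1 (1.82-fold) higher. WNT targets had 2 of 12 higher and 4 lower (9 adjusted over the list alone, median -0.21, camera adjusted p = 0.194), the falls including the WNT antagonist DKK1 (1.92-fold), LGR5 (1.87-fold, detected on 1 of 3 sorafenib arrays) and cyclin CCND1 (1.53-fold).

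Metabolic enzymes of hepatocytes rose with a median of 0.44, 8 of 14 higher and 2 lower (11 adjusted over the list alone, camera adjusted p = 0.0461, adjusted p = 0.345 with an estimated correlation), a call lost in 2 of the 6 fits without 1 array, with array weights, with detection required on all 6 arrays and without the filter on dim probes, where the median was 0.07. The urea cycle gene ASS1 rose 3.09-fold, the tyrosine catabolism genes TAT at least 1.22-fold and HPD 1.79-fold. Hepatocyte secreted proteins and markers had 5 of 23 higher and 5 lower (10 adjusted over the list alone, camera adjusted p = 0.916), with SERPINC1 and the apolipoprotein APOC3 (1.63-fold) higher. F2, the prothrombin gene, differed by 0.83 without passing. The median of this list was -0.01, its mean 0.15 and camera's direction downward. Liver transcription factors had 2 of 11 higher and 4 lower (6 adjusted over the list alone, median -0.09, camera adjusted p = 0.569), with CEBPA up by 0.41, PROX1 at -0.80 and NR0B2 at -0.39 past the threshold. Cholangiocyte and progenitor markers fell, 4 of 6 lower (4 adjusted over the list alone, median -0.29, camera adjusted p = 0.0265, adjusted p = 0.165 with an estimated correlation), among them SOX9 (2.02-fold), KRT19 (1.67-fold) and CD24 (1.28-fold); without the filter on dim probes the list did not pass (median -0.16).

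Metallothioneins and metal handling genes rose with a median of 0.23, 5 of 12 higher and none lower (7 adjusted over the list alone, camera adjusted p = 0.0110, adjusted p = 0.232 with an estimated correlation), including MT1G, MT1F (at least 1.81-fold) and MT1E (1.91-fold); with detection required on all 6 arrays the list did not pass (median 0.18). Cytosolic heat shock genes fell, 8 of 16 lower and none higher (9 adjusted over the list alone, median -0.30, camera adjusted p = 0.000285, adjusted p = 0.117 with an estimated correlation), with DNAJB1 down 1.61-fold, CHORDC1 1.48-fold and CRYAB at least 1.31-fold. NRF2 targets had 9 of 20 higher and 4 lower (14 adjusted over the list alone, median 0.04, camera adjusted p = 0.343), including AKR1B10 (1.85-fold) and UGDH (1.53-fold) higher and PRDX1 (1.56-fold) lower. Ribosomal protein genes rose slightly, by a median of 0.18, with 12 of 36 higher and none lower (14 adjusted over the list alone, camera adjusted p = 0.000668, adjusted p = 0.117 with an estimated correlation). RPL12 rose 1.52-fold, RPLP1 1.37-fold and RPL37, on a dim probe, 1.89-fold, and centring on the tested probes lowered the list's median to 0.10. Ribosome biogenesis factors had 1 of 27 higher (WDR12, 0.42) and 2 lower (MRTO4, -0.44, and NIP7, -0.42), with a median of -0.06 (3 adjusted over the list alone, camera adjusted p = 0.494).

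Housekeeping genes had 3 of 12 lower and none higher (3 adjusted over the list alone, median -0.10, camera adjusted p = 0.241), namely HPRT1 (-0.37), POLR2A (-0.31) and YWHAZ (-0.30, with a second probe at 0.34 that did not pass). Of the markers of other cell types, no endothelial gene of 12 was measured. Leukocyte markers had 1 of 5 higher and 2 lower (3 adjusted over the list alone, median -0.13, camera adjusted p = 0.272), with LYZ down 3.52-fold, AIF1 down 1.38-fold (a second probe at 0.31 did not pass) and CD14 up 1.35-fold. Both measured fibroblast markers fell, LUM 1.51-fold and PDGFRB at least 1.56-fold (2 adjusted over the list alone), in step with the fall of the TGF-beta and mesenchymal list. Of the 2 measured markers of cervical and kidney lines, CDKN2A fell by 0.29 on the log2 scale (a second probe at -0.28 did not pass) and VIM differed by 0.17 (1 past when adjusted over the list alone).

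In all, 17 of the 37 tested lists passed with camera, 7 higher and 10 lower. With an estimated correlation 4 passed, namely the integrated stress response, both cell cycle lists and cholesterol synthesis. With undetected genes set at their bounds, list medians became -0.35 for TGF-beta, -0.53 for NF-kB, -0.58 for histones, 0.32 for hepatocyte enzymes and 0.14 for interferon. Without the filter on dim probes 3 further medians moved while the calls held, to -0.10 for TGF-beta, -0.35 for NF-kB and -0.31 for histones. Where the probes of a gene disagreed, the call rests on the brightest: for ERBB3 that probe was higher (0.39) and the others lower (-0.76 and -0.58), all past the threshold.

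**Figure D4:**
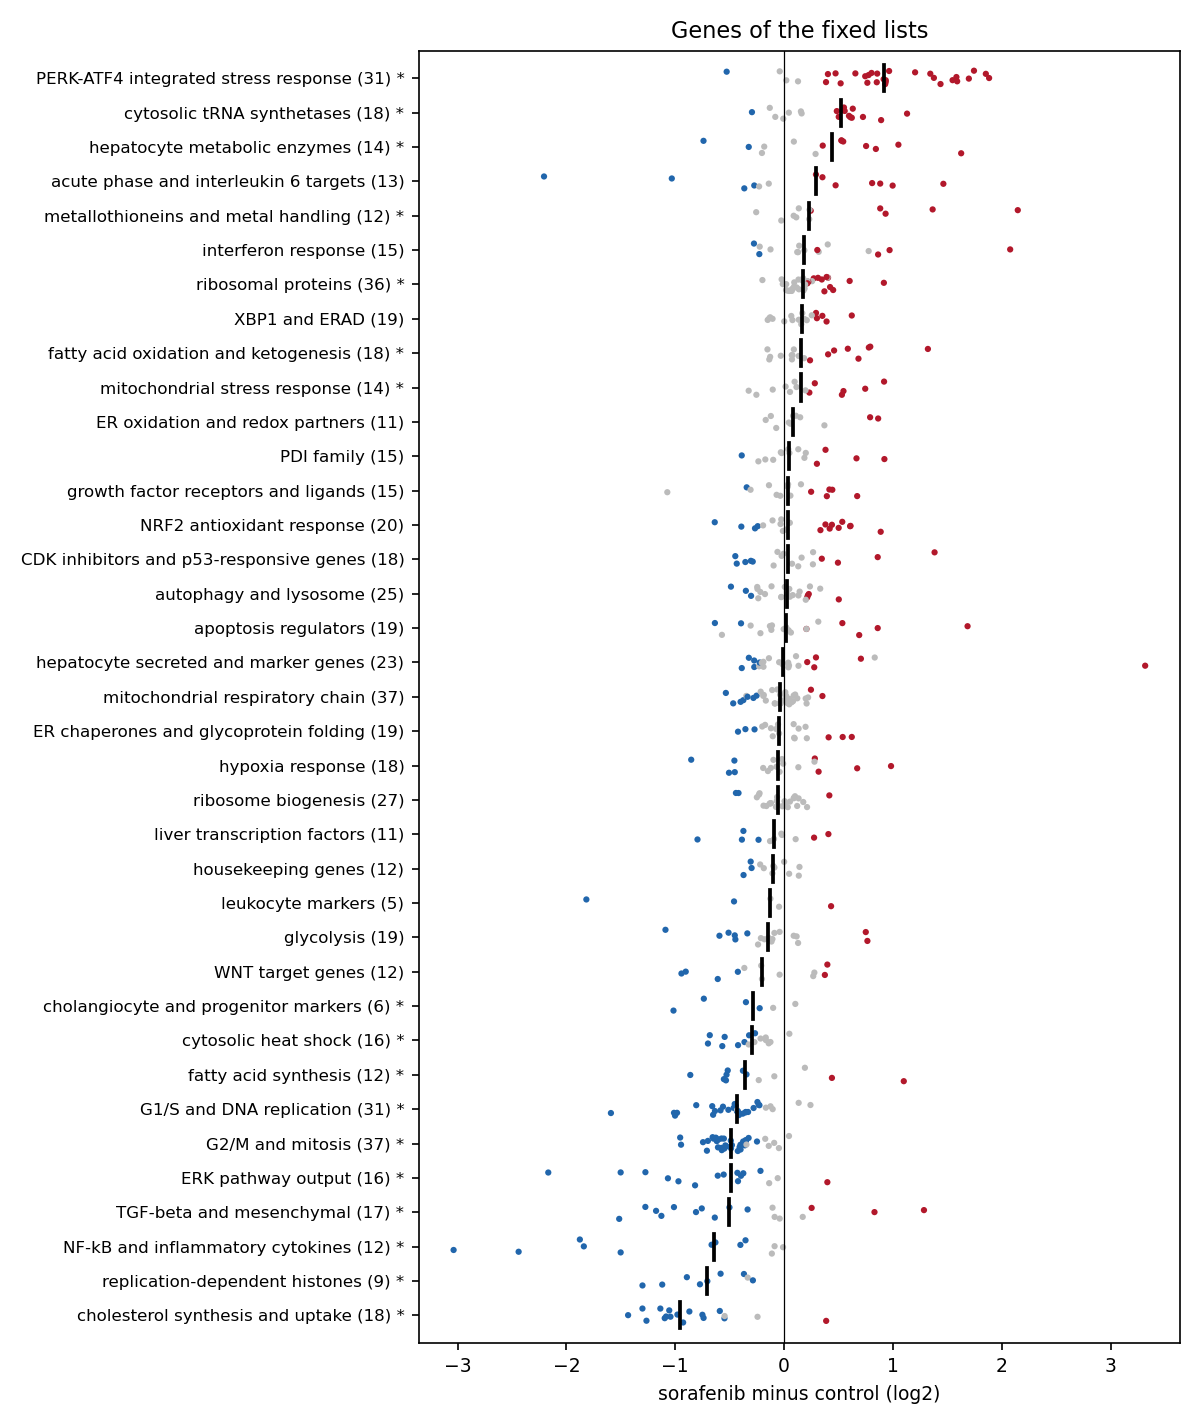
Each point is a measured gene of a list (y axis, number of measured genes in parentheses), placed at its difference sorafenib minus control (log2, x axis) and coloured red for higher, blue for lower and grey for not past an adjusted p of 0.05; black bars are list medians and vertical scatter carries no meaning. Asterisks mark the 17 lists that passed with camera, from the integrated stress response at 0.91 to cholesterol synthesis at -0.95, of which 4 also passed with an estimated correlation.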

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

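Centring on the tested probes was the only alternative chosen after the data had been seen. Over the alternatives, the probes past the threshold ranged from 4030 to 6697, the genes from 2717 to 4466 and the PDI genes from 3 to 6 (3 to 5 over the fits without 1 array). The lists past the threshold ranged from 14 to 18, apart from 4 with an estimated correlation, which asks the same question of the lists, and 33 with fry, which asks another. Of the 17 lists called, 12 passed at the preset correlation under every alternative. Without the filter on dim probes the medians were -0.162 for cholangiocyte markers and 0.0658 for hepatocyte enzymes, neither past the threshold, and -0.35, -0.10 and -0.31 for NF-kB, TGF-beta and histones, still past it; this setting adds undetected genes to the lists. With detection required on all 6 arrays, fatty acid synthesis (-0.362), hepatocyte enzymes (0.355) and metallothioneins (0.183) no longer passed. Centring on the tested probes ended the calls of fatty acid synthesis (-0.364) and mitochondrial stress (0.125), array weights that of hepatocyte enzymes (0.368), and median centring (0.211) and the median over a gene's probes (0.202) that of mitochondrial stress. Without 1 array, medians ran from -0.376 to -0.341 for fatty acid synthesis, 0.384 to 0.445 for hepatocyte enzymes and 0.131 to 0.171 for mitochondrial stress, each with some fits not past the threshold; these fits have fewer samples. The cause of the other lost calls was not tested. Genes differing at least 2-fold numbered 150 with normexp at an offset of 50 in place of 16, 132 with no background correction and 132 in the deposited log2 values, which are the same processing; the offset and the background method were not varied separately, and the cause was not tested. Probes detected in only 1 group numbered 291 when a detection p under 0.05, in place of 0.01, sufficed in that group. The median over a gene's probes reversed ERBB3 (-0.759) and YWHAZ (0.0194), whose probes disagree. Among the other single-gene results under alternatives, 4074 kept direction and side of the threshold, 142 lost the call and 93 gained it.

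Same-numbered samples were not shown to be paired: their deviations from the group means correlated at 0.089, 0.102 and 0.252, and control 1 correlated better with sorafenib 2 (0.094) than with its own number. Replicate 3 of each group correlated negatively with replicates 1 and 2 of the other (-0.174 to -0.136), in part because deviations cancel within a group. The samples numbered 3 deviated partly alike (0.252), and the second principal component set both apart. What these samples share was not tested. With the replicate number as a block, 5519 probes, 3634 genes and 14 lists passed, and fatty acid synthesis (-0.362), hepatocyte enzymes (0.441) and mitochondrial stress (0.155) did not. A slide or scan date block was not run, since the sources used here give neither. Signal over background limits the rest: 34.3% to 36.7% of probes were detected on an array, and for genes undetected in a group only a bound is known.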

Other observations

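The family scan, the tests on other 5' TOP genes and the choice of the snoRNA host genes came after the data had been seen, and the genes in the next paragraph were chosen after their values were seen.

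CREB3L3, a liver transcription factor anchored in the ER membrane, rose by 1.83 ± 0.12 (log2, SE), ACACB, the mitochondrial acetyl-CoA carboxylase, by 1.61 ± 0.11, ACAD11 by 1.65 ± 0.09 and CHCHD10, a mitochondrial protein, by 1.60 ± 0.07. The methionine adenosyltransferase gene MAT1A, undetected in control cells, rose at least 1.73-fold. Among single genes that fell were the chemokine CXCL6 (-1.60 ± 0.09), LTB (-1.66 ± 0.10), NPPB (-1.61 ± 0.09) and the endothelin receptor EDNRB (-1.44 ± 0.10), and the chemokine receptor CXCR4, undetected with sorafenib, fell at least 1.77-fold. Limma's adjusted p for these genes was at most 0.000535, and they were not tested as groups.

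Genes were also grouped by the stem of their symbol, giving 132 stems with at least 10 tested genes. Past the threshold with camera stood the H stem, mostly histones, and the SNHG stem, host genes of small nucleolar RNAs (Benjamini-Hochberg adjusted p = 0.000195 and 0.000740), and 0 stems with an estimated correlation (adjusted p = 0.998 for both). Of 12 SNHG genes 8 rose and none fell, with a median of 0.46 at fitted values. They were led by SNHG5 (1.40), SNHG32 (0.95), SNHG8 (at least 1.17-fold, undetected in control cells) and SNHG7 (0.87). Poly(ADP-ribose) polymerase genes had 7 of 11 higher (camera adjusted p = 0.105) and PSMD proteasome subunits 6 of 11 lower (camera adjusted p = 0.0790), neither past the threshold as a stem. The medians of the SNHG, PARP and PSMD stems kept their signs under the 5 other distinct scalings tried.

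The 6 arrays can be divided into 3 and 3 in 10 ways, and 1 of the 10, the real one, gave as many probes past the threshold (5778, against 0 in the highest of the others by limma). So few divisions cannot give a share under 0.05.

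The integrated stress response rose while the list of ER chaperones did not pass, and the per-array difference of the list means was higher by 0.90 with sorafenib (SD 0.02 in each group). Compression of bright probes is argued against, because the 22 stress response genes at least as bright as the median chaperone had a median difference of 0.853. Background correction is argued against too, since the list medians differed by 0.881 or more under 3 distinct alternatives (the deposited values repeat the analysis without background correction), against 0.960. Among these, only cyclic loess changed the between-array normalization. A scaling common to all genes of an array cancels in such a difference, so normalization was tested only weakly. The permutation test of that difference decided nothing, since its exact two-sided p of 0.1 is the smallest that 3 against 3 can give. A response of the ATF4 arm without the chaperone arm stays a hypothesis. Of the 19 chaperone genes 3 rose (DNAJB9 and HYOU1 among them) and 3 fell (MANF, DNAJC3 and SDF2L1), so part of that arm may have responded as well.

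The ribosomal protein list rose by 0.18. A trend with probe brightness is argued against, since 0 of 10000 intensity-matched lists had a median as high, and so is the normalization, since the smallest rise over 4 distinct alternatives was 0.173, although centring on the tested probes, added later, gave 0.10. A candidate explanation is a rise of messages with a 5' terminal oligopyrimidine (TOP) tract in general: 18 other such genes had a median of 0.184 (camera p = 0.0115, but p = 0.125 with an estimated correlation), which was 0.08 with centring on the tested probes. Some of those genes' values had been seen before that test was written, 5 of the 18 rose and 1, HNRNPA1, fell. Cross-binding among ribosomal protein genes and pseudogenes was not tested.

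For the SNHG genes, a trend with brightness is argued against, since 2 of 10000 matched lists had a median as high. The stem was picked for its rise from 132 stems in these data, and that share makes no allowance for the choice. It therefore does not measure how unusual the rise is. Of 5 measured host genes outside that stem, 3 rose, ZFAS1 (1.50), EPB41L4A-AS1 (1.24) and TAF1D (at least 1.10-fold), but the 5 did not pass as a list, and their median of 0.54 was 0.24 without background correction. Many such host transcripts are substrates of nonsense-mediated decay, and weaker decay could explain a rise. The prediction was that it would also raise the pathway's factors, taken to be among its own substrates. That rise was not seen: the 6 measured factors had a median of -0.0776 (SD of the 6, 0.10), with 5 below 0. This was under the 0.05 set beforehand and at most 0.01 under any scaling tried. An interval added after that median was seen, the 95% interval of the difference in per-array medians (-0.07), ran from -0.19 to 0.0545. It lay below the rise of 0.15 that had been predicted. Decay itself was not measured, and not every factor need be a substrate. The test therefore cannot decide whether decay weakened, and what raised the SNHG genes stays open.

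The fall of the cholesterol list was put to the same 2 tests as the ribosomal proteins: 0 of 10000 matched lists had a median as low, and the median was -0.76 to -0.97 over 4 distinct alternatives.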
